A study of Rattus norvegicus with 34 samples.

How the data were processed

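Methylated DNA immunoprecipitation sequencing (MeDIP-seq) was used by the study to profile sperm of outbred Sprague Dawley rats. In MeDIP-seq an antibody against methylated cytosine pulls down methylated DNA fragments before sequencing. The read density over a stretch of genome then rises with its methylation, and also with its density of methylatable sites and its copy number. Sperm came from the cauda epididymis, where mature sperm are stored. Per the labels' protocols, somatic cells were removed by brief sonication and washing, and DNA of several males was pooled before the pull-down. An F1 pool held 3 to 4 males and an F2 ifosfamide pool held 8 to 9 males.

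Counts were used for 18 of the 34 libraries in the labels, namely 6 F1 control, 6 F1 ifosfamide and 6 F2 ifosfamide pools. The other 16 libraries, from F0 males and F2 control pools, were not analysed here. Per the submitters' processing notes, FastQC, Trimmomatic, Bowtie2, SAMtools and edgeR were used with the Rnor_6.0 genome build. Their versions and settings are not given in the sources used here.

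Both deposited tables hold the authors' read counts per 1 kb window and library, named as counts in the file headers. Their values are whole numbers with a different total in each library, as counts without normalization would have. The 2782040 windows of 1000 bases cover chromosomes 1 to 20, X, Y and the mitochondrial genome (MT). The tables share the 6 F1 control libraries, and all 6 control columns were identical in both, so the tables were joined. RPKM values deposited by the authors beside the counts, per the file headers, are on the reads-per-kilobase-per-million scale. They were used only to recover each library's number of reads. A read was counted in 1.16 to 1.25 windows on average, so counts of adjacent windows are not independent. The authors' deposited log2 fold changes and the authors' deposited p-values, from edgeR per the file headers, were used only to be set beside the fit made here. Those log2 values were turned to ifosfamide over control. Their sign was checked for the F1 table against counts divided by library totals. For the F2 table the turned values correlated with the fit made here at r = 0.9999. The authors' deposited table gives p-values for windows with a total of at least 120 counts over its 12 libraries.

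Each comparison was fitted on the deposited counts with edgeR 4.0.16 in R 4.3.3, using TMM normalization. Windows were kept by the filterByExpr rule with a minimum count of 10. The quasi-likelihood test was two-sided, without covariates, on the 12 pools of the comparison, and p was adjusted by the Benjamini-Hochberg method over all windows tested. Windows with an adjusted p below 0.05 are called here. The number below an unadjusted p of 1e-04 is given beside them, with the number that chance would give. Normalized signal is given on the TMM-scaled counts-per-million (CPM) scale, as mean and SD over 6 pools per group. Fold changes are on the log2 scale and each has its standard error (SE).

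Called windows at most 1 kb apart were merged into regions. The named regions follow a rule set before the data were examined, which takes the 10 strongest higher and the 10 strongest lower regions of each comparison by the p of their strongest window, on chromosomes 1 to 20, X and Y. Windows named outside that rule are the windows called in both comparisons with the control, the called MT windows and the clusters, which were chosen after their values were seen. No annotation of the Rnor_6.0 build was used here, so regions are given by coordinates, counted from 1, without gene names. For the same reason the planned tests of promoters, gene lists and marker lists of other cell types were left out.

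Both comparisons with the control use the same 6 control pools. Their overlap was therefore set beside 3 simulated pairs of unchanged groups against those controls, the overlap of independent lists, and the 10 splits of the controls into 3 and 3. In each split control pool 1 was among the controls of F1. Called windows were compared with other tested windows per chromosome by Fisher's exact test, with Benjamini-Hochberg adjustment over 23 chromosomes. The share of counts in the highest 10% of windows and on X, Y and MT was compared between groups by exact two-sided permutation tests over all 924 splits of 12 pools, adjusted over 12 tests. Clusters are runs of at least 5 windows called in the same direction in either comparison with the control, with the starts of successive called windows at most 100 kb apart. A window was termed isolated where its total over the 18 libraries was at least 10 times the total of either neighbouring window.

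Libraries held 23336048 to 39440265 window counts, with a median of 5 to 8 counts per window. On simulated counts with 200 changed windows, the fit recovered 4.48% of 1.5-fold, 41.8% of 2-fold and 92.4% of 3-fold changes for F1 ifosfamide against F1 control. It recovered 5.97%, 59.7% and 89.4% of the same fold sizes for F2 ifosfamide against F1 control, and 4.48%, 52.2% and 89.4% for F2 against F1 ifosfamide. In that order of comparisons, 6 of 98, 5 of 108 and 12 of 109 simulated calls were at unchanged windows. Changes of 1.5-fold were mostly missed in these simulated counts, which held no gradient among libraries, so recovery in the real data may differ. Replicates were checked for repeated libraries over 45 pairs within groups. Their chi-square per degree of freedom was 1.05 to 1.72, with no pair at sampling noise alone, and all 18 libraries were kept as separate replicates. On the first component of variation within groups, F1 ifosfamide pools 1 and 2 scored -157 and -119 and the other pools of that group 81.4 to 314, and F1 control pools 4 and 6 scored -133 and -153 and the other control pools 21.0 to 208. Whether pools of a group hold different males is not given in the sources used here, and the labels list fewer F2 ifosfamide males than 6 pools of that size would need, so F2 pools may share males. The labels also give few F0 founders per lineage, so pools of a lineage share ancestors. The p-values treat pools as independent, measure only the spread between these pools and do not cover differences between founder families. No batch is given in the labels.

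The alternatives tried were other normalizations (DESeq2 size factors, library size alone, loess offsets by abundance), other filters, other tests (edgeR's exact test, limma 3.58.1, DESeq2 1.42.0), a replicate block, other thresholds, a fit of all 3 groups and leaving out each pool. A covariate from the first component of variation within groups, a covariate of windows per read, and leaving out the pool farthest from its group mean were added after the data were seen.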

Results

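The study treated pubertal male rats of the F0 generation with ifosfamide, an alkylating chemotherapy drug, or with phosphate-buffered saline, and then bred untreated F1 and F2 generations from them. Injections of 8.5 mg/kg ifosfamide or 1.1 mL/kg saline were given on days 26, 29 and 32 of age. DNA methylation in sperm of the descendants was measured by MeDIP-seq over 1 kb windows of the Rnor_6.0 genome. The groups were 6 F1 control pools, 6 F1 ifosfamide pools and 6 F2 ifosfamide pools. Total counts over all windows were 23336048 to 34051679 in F1 control libraries, 25531658 to 39440265 in F1 ifosfamide libraries and 27424144 to 36309987 in F2 ifosfamide libraries. Between 9.72% and 13.5% of windows had 0 counts in a library. F1 ifosfamide pools 1 and 2 lay close to each other and apart from pools 3 to 6, with a chi-square per degree of freedom of 1.08 between them and 1.36 to 1.72 against the others.

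The first comparison asked whether sperm of F1 males differed between the ifosfamide and control lineages. Most regions that differed carried less MeDIP signal in the ifosfamide lineage. The strongest region lay on the X chromosome at 30735001 to 30737000, and in its strongest window, which starts at 30735001, the signal was 2.43 ± 0.771 CPM (SD, n = 6) in control pools and 0.951 ± 0.101 CPM in ifosfamide pools. All ifosfamide pools lay below all control pools there (log2 fold change -1.35, SE 0.16, adjusted p = 9.82e-07 by edgeR's quasi-likelihood test). A window on chromosome 14 at 54147001 to 54148000 fell from 13.3 ± 5.54 to 5.68 ± 2.15 CPM (log2 fold change -1.23, SE 0.17, adjusted p = 5.65e-05). A region on chromosome 16 with its strongest window at 51028001 to 51029000 had the highest signal of the named lower regions and fell from 30.0 ± 7.99 to 16 ± 2.76 CPM, with no overlap between the pools (log2 fold change -0.90, SE 0.14).

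The other named lower windows of the F1 comparison started at 112120001 and 111855001 on chromosome 10, 99152001 on chromosome 7, 39108001 on chromosome 16, 127567001 on chromosome 2, 49407001 on chromosome 12 and 109827001 on X. Their log2 fold changes ran from -1.73 on chromosome 16 to -0.93 on chromosome 2. These 7 windows and that at 54147001 on chromosome 14 were isolated, with at least 10 times the counts of either neighbouring window over the 18 libraries, so that 8 of the 10 named lower windows were of this kind and none of the named higher ones. The window at 54147001 held 6831 counts in all, between neighbours with 3 and 80 counts. The windows at 30735001 on X and 51028001 on chromosome 16 were not isolated.

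Fewer regions carried more signal in F1 ifosfamide sperm. The strongest, on chromosome 7 at 61605001 to 61606000, rose from 0.398 ± 0.0913 to 0.985 ± 0.131 CPM, with no overlap between the pools (log2 fold change 1.30, SE 0.20, adjusted p = 0.00036 by edgeR's quasi-likelihood test). A window on chromosome 12 at 22713001 to 22714000 rose from 0.378 ± 0.212 to 0.969 ± 0.273 CPM (log2 fold change 1.36, SE 0.23). A region on chromosome 1 with its strongest window at 11908001 to 11909000 rose from 18.1 ± 6.62 to 33.4 ± 9.29 CPM (log2 fold change 0.88, SE 0.15). The others started at 91130001 on chromosome 5, 46330001 on chromosome 14, 61716001 on chromosome 18, 78049001 on chromosome 2, 61168001 and 145647001 on chromosome 7 and 57194001 on chromosome 17, with log2 fold changes of 0.86 to 1.43. The calls at 91130001 on chromosome 5, 11908001 on chromosome 1 and 54147001 on chromosome 14 ended with DESeq2's Wald test and with edgeR's exact test. That of 109827001 on X ended with the former, and those of 145647001 on chromosome 7 and 39108001 on chromosome 16 with the latter. A covariate for the number of windows counted per read ended the calls at 46330001 on chromosome 14 and 78049001 on chromosome 2, and that at 39108001 on chromosome 16, where the log2 fold change became -0.81. Leaving out control pool 6 ended the call at 57194001 on chromosome 17 (log2 fold change 0.83 without it), and leaving out control pool 2 ended that at 145647001 on chromosome 7 (1.06 without it).

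Of 1043656 windows tested between F1 ifosfamide and F1 control, 624 were called, 57 higher and 567 lower in ifosfamide, which is 90.9% lower. They merged into 573 regions, of which 525 were a single window, and their median absolute log2 fold change was 0.80. In 139 called windows (22.3%) the 6 ifosfamide pools did not overlap the 6 control pools, which chance gives in 0.216% of windows not selected for a difference, as these were. At an unadjusted p of 1e-04 there were 1073 windows, 121 higher and 952 lower, where chance gives 104. The authors' deposited table gives 223 windows at an adjusted p of 0.05, 36 higher and 187 lower in ifosfamide, and 181 of them were also called here. The number was 333 with DESeq2's Wald test, 222 with edgeR's exact test, 229 with limma, 238 with a minimum count of 30, 1010 with all 3 groups in 1 fit, 1938 with a covariate from the first component of variation within groups and 1996 without the pool farthest from the mean of each group. With windows per read as a covariate 609 were called, 169 higher and 440 lower, and 253 of them were among the 624. The number called here rested on single pools, being 2117, 352, 389, 173 and 178 without control pools 1, 2, 3, 4 and 6, and 1808, 159, 966 and 309 without ifosfamide pools 1, 3, 4 and 6. At the unadjusted threshold it was 2155, 596 and 660 without control pools 1, 4 and 6, and 1947 and 623 without ifosfamide pools 1 and 3.

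The second comparison set F2 ifosfamide sperm against F1 control sperm, so that lineage and generation differ together. The strongest region carried more signal in F2 ifosfamide pools and lay on chromosome 2 at 155784001 to 155785000. Its signal was 1.72 ± 0.537 CPM in F1 control pools and 4.53 ± 1.94 CPM in F2 ifosfamide pools (n = 6 each, log2 fold change 1.39, SE 0.15, adjusted p = 8.67e-10 by edgeR's quasi-likelihood test). A region on chromosome 9 with its strongest window at 103428001 to 103429000 rose from 3.15 ± 0.72 to 6.47 ± 2.40 CPM, and a window on chromosome 8 at 7027001 to 7028000 rose from 0.399 ± 0.139 to 1.24 ± 0.65 CPM. The strongest lower window, on chromosome 1 at 54181001 to 54182000, fell from 2.09 ± 0.558 to 1.10 ± 0.399 CPM (log2 fold change -0.91, SE 0.15, adjusted p = 0.00102). A window on chromosome 14 at 59629001 to 59630000 fell from 0.735 ± 0.159 to 0.278 ± 0.115 CPM, with no overlap between the pools.

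The other named higher windows of the F2 comparison started at 45928001 on chromosome 20, 145601001 and 145646001 on chromosome 7, 11966001 on chromosome 1, 50419001 on chromosome 19, 36093001 on chromosome 3 and 36270001 on chromosome 4, with log2 fold changes of 0.84 to 1.86. The largest of these, at 50419001 on chromosome 19, was uneven within groups, with 1.01 ± 1.72 CPM in control pools and 3.46 ± 3.12 CPM in F2 ifosfamide pools. The other named lower windows started at 119866001 on chromosome 9, 55649001 and 56026001 on chromosome 1, 169329001 on chromosome 3, 141796001 on chromosome 7, 69506001 on chromosome 5, 40879001 on chromosome 18 and 75574001 on chromosome 8, with log2 fold changes of -1.13 to -0.70. The window at 36093001 on chromosome 3 was isolated, with 3442 counts between neighbours with 76 and 2 counts.

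Only 4 of the 20 named windows of the F2 comparison, at 7027001 on chromosome 8, 54181001 on chromosome 1, 59629001 on chromosome 14 and 69506001 on chromosome 5, stayed called under every alternative that tested them. All but 54181001 among these were not tested with a minimum count of 30 and had no adjusted p with DESeq2's Wald test. DESeq2's Wald test ended the call of 8 of the 10 named higher windows, all but the untested ones at 7027001 on chromosome 8 and 145601001 on chromosome 7, and so that of the strongest window, at 155784001 on chromosome 2. It also ended those at 141796001 on chromosome 7 and 40879001 on chromosome 18. Among the lower windows, the call at 119866001 on chromosome 9 ended without control pool 2 (log2 fold change -0.96 without it), and that at 55649001 on chromosome 1 without control pool 3 (-0.72). The call at 56026001 on chromosome 1 ended without control pool 3 (-0.62) or F2 ifosfamide pool 4 (-0.58), and that at 75574001 on chromosome 8 without F2 ifosfamide pool 3 (-0.79). At 141796001 on chromosome 7 it ended without control pool 2 (-0.78) or F2 ifosfamide pools 3 (-0.78) or 4 (-0.76), and at 40879001 on chromosome 18 without control pool 3 (-0.67) or F2 ifosfamide pools 3 (-0.70), 4 (-0.74) or 5 (-0.72). The other alternatives that ended calls were edgeR's exact test, limma, a minimum count of 30, a fit of all 3 groups and a covariate from the first component of variation within groups.

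Of 919249 windows tested between F2 ifosfamide and F1 control, 286 were called, 171 higher and 115 lower in F2 ifosfamide. Most were instead lower with edgeR's exact test (103 higher, 116 lower), a minimum count of 30 (22 and 24) and without the pool farthest from the mean of each group (391 and 473). They merged into 264 regions with a median absolute log2 fold change of 0.83 over called windows, and in 103 called windows (36.0%) the groups did not overlap. At an unadjusted p of 1e-04 there were 886 windows, 451 higher and 435 lower, where chance gives 91.9. Over 1 in 5 of the tested windows, 5 of 100 divisions of the pools, the real one included, gave at least as many at either threshold, so chance was not excluded for these counts. The authors' deposited table gives 206 windows at an adjusted p of 0.05, 102 higher and 104 lower, and 134 of them were also called here. The number was 27 with DESeq2's Wald test, 58 with limma, 56 with all 3 groups in 1 fit and 86 with a covariate from the first component of variation within groups. It was 714 with the replicate number as a block, although replicate numbers did not pair the pools. The number called here was 175, 72, 165, 734, 138 and 783 without control pools 1 to 6 in turn, and 1501, 74, 83, 98 and 112 without F2 ifosfamide pools 1, 3, 4, 5 and 6. At the unadjusted threshold it was 564 and 1391 without control pools 2 and 6, and 1751, 542, 578 and 578 without F2 ifosfamide pools 1, 3, 4 and 5.

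**Figure D1:**
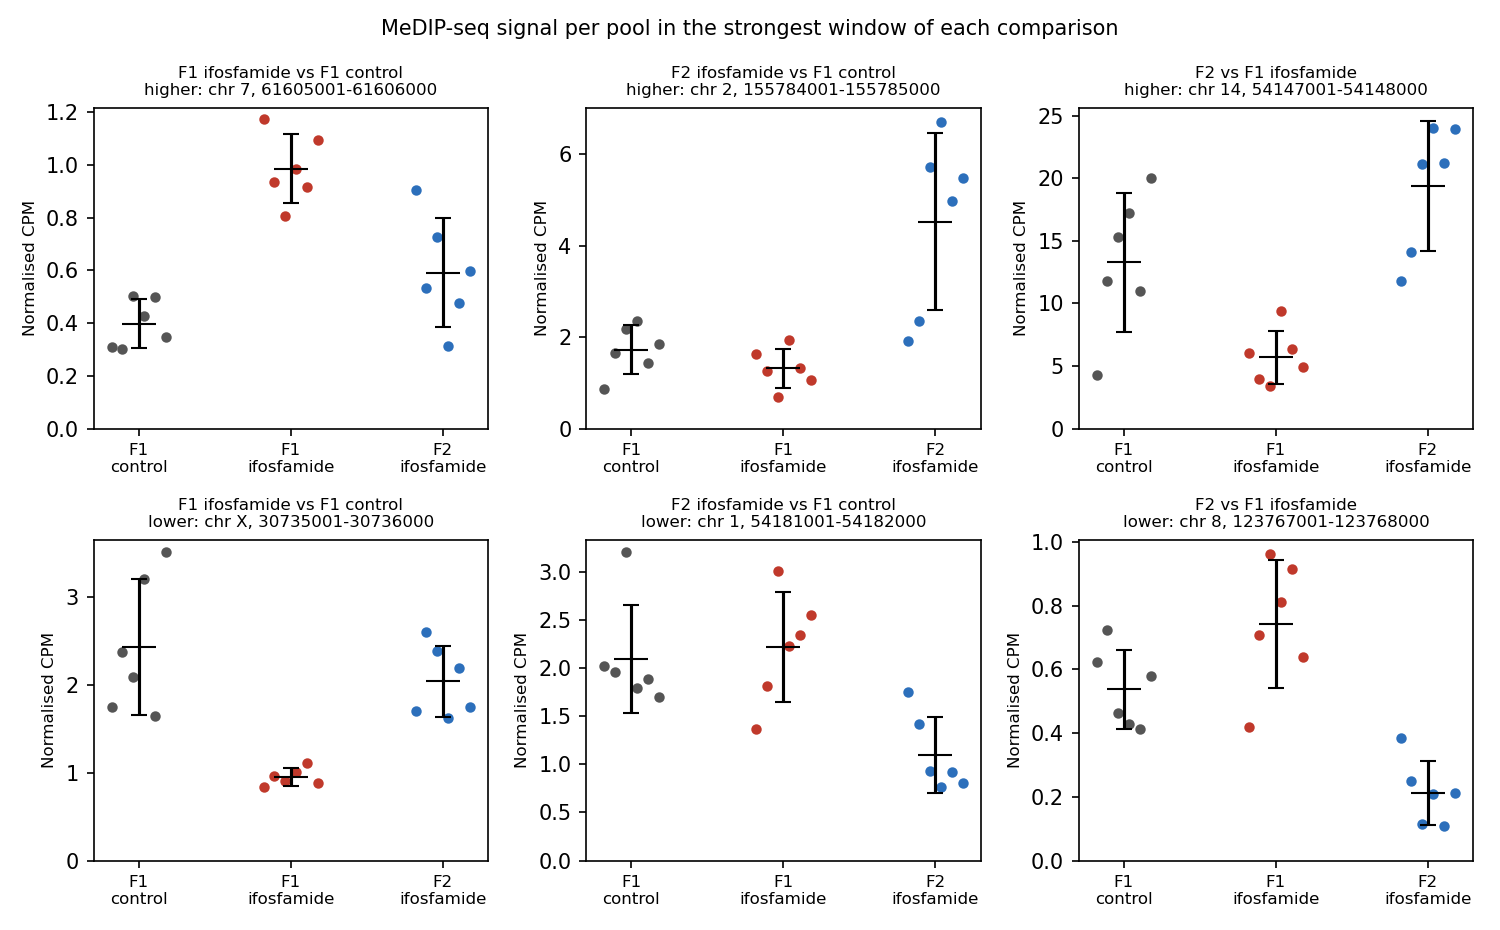
MeDIP-seq signal per pool, in normalized CPM on axes starting at 0, in the strongest higher window (top) and the strongest lower window (bottom) of each comparison. Points are the 6 pools of each group, horizontal lines the mean and error bars the SD, and the F1 ifosfamide pools lay below all F1 control pools in the chromosome X window.

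Windows called in both comparisons with the control were few. In 8 of them signal was higher in both ifosfamide groups, at 61898001, 145310001, 145498001, 145566001 and 145647001 on chromosome 7, 22713001 on chromosome 12, and 46638001 and 46682001 on chromosome 14. In 2 it was lower in both, at 73275001 on chromosome 7 and 119866001 on chromosome 9. In a further 2, at 36093001 on chromosome 3 and 36270001 on chromosome 4, it was lower in F1 ifosfamide (log2 fold changes -1.02 and -0.74) and higher in F2 ifosfamide (0.91 and 0.84).

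The 10 windows called in the same direction compare with 0 to 1 in simulated unchanged groups against the same controls, whose own lists held only 0 to 1 windows, and with 0.00913 higher and 0.0719 lower windows for independent lists. Independent lists treat windows as separate. Shared windows at 145498001, 145566001 and 145647001 on chromosome 7 and 46638001 and 46682001 on chromosome 14 lay in clusters described below. When the controls were split into 3 and 3, the overlap was 0 to 1 over 10 splits with a median of 0. The F1 list was shorter than that of all 6 controls in all 10 splits and the F2 list in 8. Control pool 1, the control farthest from its group mean, served F1 in every split and never F2. The splits are therefore uneven, and their overlap and covariance cannot decide whether F1 and F2 share changes. The covariance of the log2 fold changes of both comparisons over 904952 windows was 0.0151 (r = 0.271), against 0.0237 (r = 0.528) in simulated unchanged groups, a difference of -0.00866. With split controls it had a median of -0.0044 and ran from -0.0145 to 0.00167. Over the whole genome, the covariance of F1 and F2 fold changes lay below that of the simulation. Simulated windows were drawn independently, without a gradient among libraries, so the simulation cannot decide whether F1 and F2 share a change.

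Some of the higher windows lay in 3 clusters, on chromosomes 1, 7 and 14, which held 6, 3 and 13 of the 57 higher windows of F1 and 4, 11 and 8 of the 171 of F2. On chromosome 1 at 11903001 to 11969000 (66 kb), 10 windows were called in either comparison with the control, on chromosome 7 at 145498001 to 145669000 (171 kb) 11 windows, and on chromosome 14 at 46518001 to 46684000 (166 kb) 19 windows. The tested windows in these clusters that were not called mostly lay above 0 as well. Their median log2 fold change in F1 ifosfamide was 0.27, 0.57 and 0.22 in that order, and in F2 ifosfamide 0.31, 0.60 and 0.24. Within 500 kb on either side the medians in F2 were 0.06, 0.07 and 0.01, and in F1 that of chromosome 1 was 0.02 and the others lay within 0.01 of 0. The windows of chromosome 7 end at 145730000, close to the end of its cluster, so the flank there lay mostly on 1 side.

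**Figure D2:**
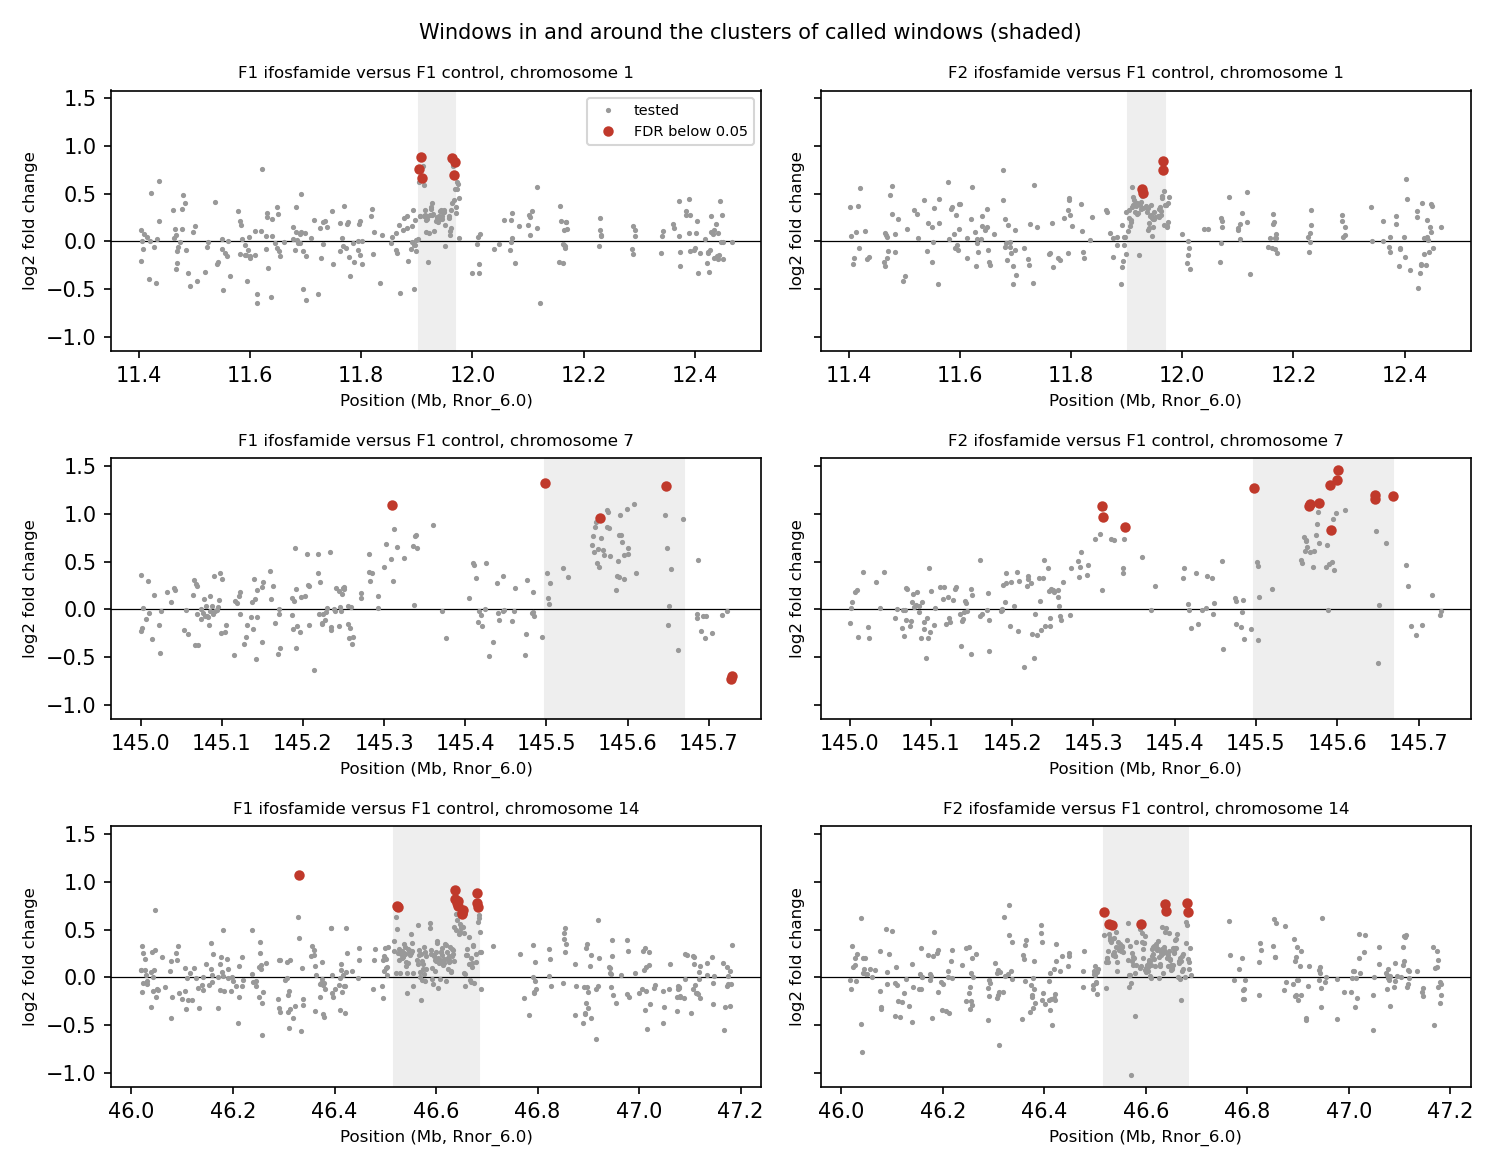
Log2 fold change against position in megabases on Rnor_6.0 for each tested window in and within 500 kb of the 3 clusters (shaded), for F1 ifosfamide (left) and F2 ifosfamide (right) against F1 control. Grey points are windows not called and red points are windows with an adjusted p below 0.05, and inside the shading most points lay above 0 in both comparisons.

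The comparison of F2 with F1 ifosfamide sperm asked whether the ifosfamide lineage differed between generations. The strongest window was that at 54147001 to 54148000 on chromosome 14, with 5.68 ± 2.15 CPM in F1 and 19.4 ± 5.19 CPM in F2 ifosfamide pools and no overlap (n = 6 each, log2 fold change 1.77, SE 0.14, adjusted p = 1.34e-16 by edgeR's quasi-likelihood test). The mean of the F1 control pools lay between these at 13.3 ± 5.54 CPM, with single pools overlapping both groups. Windows at 36093001 on chromosome 3 and 36270001 on chromosome 4 rose from 2.77 ± 1.43 to 10.7 ± 3.35 CPM and from 3.03 ± 0.726 to 9.08 ± 2.70 CPM. The strongest lower region had its lead window on chromosome 8 at 123767001 to 123768000, which fell from 0.742 ± 0.20 to 0.213 ± 0.101 CPM (log2 fold change -1.74, SE 0.25, adjusted p = 4.56e-06).

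The other named higher windows of this comparison started at 155784001 on chromosome 2, 3368001 on chromosome 8, 118675001 on chromosome 3, 52509001 and 28591001 on chromosome 14, 103427001 on chromosome 9 and 49407001 on chromosome 12, with log2 fold changes of 1.06 to 2.16. The other named lower windows started at 108676001 on chromosome 13, 56026001 and 262990001 on chromosome 1, 148193001 on chromosome 4, 4180001 on chromosome 14, 110107001 and 141796001 on chromosome 7, 97288001 on chromosome 9 and 63659001 on chromosome 16, with log2 fold changes of -1.61 to -0.93. All 20 stayed called without any pool and under the other settings tried for this comparison. The windows at 54147001 on chromosome 14, 36093001 on chromosome 3 and 49407001 on chromosome 12 were isolated. That at 118675001 on chromosome 3, with 733 counts in all, lay between neighbours with 0 and 102 counts. The region of 3368001 on chromosome 8 held called windows of both directions.

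Between F2 and F1 ifosfamide, 22806 of 1062540 windows were called, 13268 higher and 9538 lower in F2, in 20651 regions. At an unadjusted p of 1e-04 there were 7509 windows, 5091 higher and 2418 lower, where chance gives 106. In 6892 called windows (30.2%) the groups did not overlap. Of 558 F1 lower windows that could be tested here, 497 were higher in F2 than in F1 ifosfamide, and of 57 F1 higher windows 25 were lower in F2. By the same test 0 moved further in the F1 direction. Both comparisons use the F1 ifosfamide pools, so windows chosen in one are not independent of the other. The number called was 14464 with a minimum row total of 10 and 9777 with a covariate from the first component of variation within groups. With windows per read as a covariate it was 44730, of which 22011 were higher and 22719 lower in F2, with 19181 shared. It was 37607, 9116, 14263 and 13844 without F1 ifosfamide pools 1, 3, 4 and 6, and 15195, 9665, 10258, 15065 and 14085 without F2 ifosfamide pools 2 to 6 in turn. At the unadjusted threshold it was 11703 and 4433 without F1 ifosfamide pools 1 and 3, and 4523 and 4792 without F2 ifosfamide pools 3 and 4.

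Called windows were not spread evenly over the chromosomes. In the F1 comparison 36 of 19049 tested windows on the X chromosome were called, all lower (odds ratio 3.30, adjusted p = 6.57e-08 by Fisher's exact test), where 90.9% of all F1 calls were lower. Chromosomes 3, 10 and 19 held proportionally fewer than the rest of the genome (odds ratios 0.545, 0.529 and 0.386). These tests did not match windows on abundance, and the median log2 CPM was 1.49 in called and -0.322 in tested F1 windows. Chromosome 10 no longer passed when windows were called at an adjusted p of 0.1 (odds ratio 0.715, adjusted p = 0.12). In the F2 comparison with the control, chromosomes 7 and 14 held 30 and 22 called windows (odds ratios 1.99 and 1.95), of which 11 and 8 lay in the clusters. Neither chromosome passed with windows called at an adjusted p of 0.1 (odds ratios 1.35 and 1.32, adjusted p = 0.229 and 0.251). The mitochondrial genome held 4 called windows of 17, all higher, starting at 3001, 10001, 11001 and 14001 with log2 fold changes of 0.72 to 0.92. Between F2 and F1 ifosfamide 9 of 23 chromosomes passed, 6 with proportionally more and 3 with fewer called windows. Apart from the mitochondrial genome, their odds ratios ran from 0.891 on chromosome 2 to 1.23 on chromosome 12, and X did not pass (odds ratio 0.98). Neighbouring windows share reads, so these p-values are too small.

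**Figure D3:**
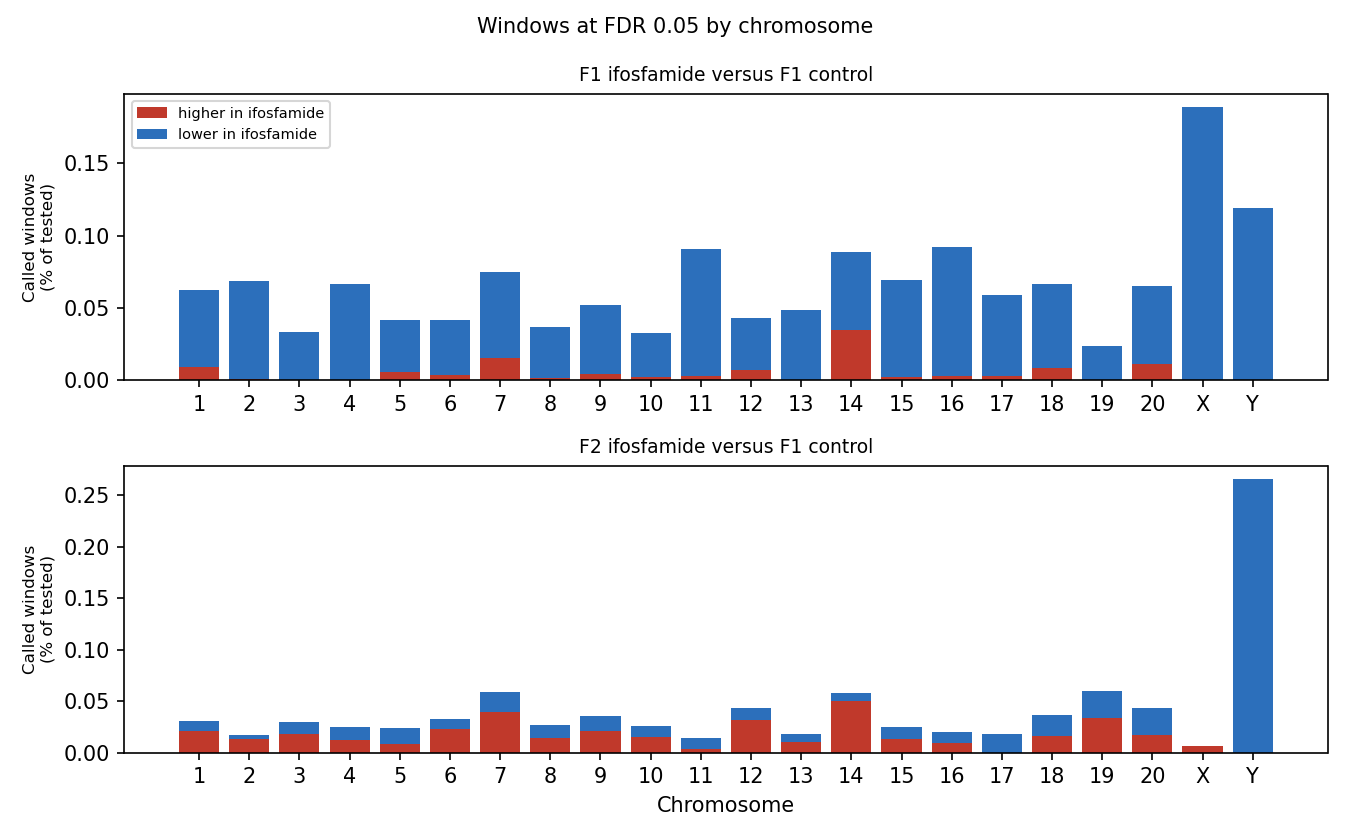
Percent of tested windows with an adjusted p below 0.05 on each chromosome, split into windows higher and lower in the ifosfamide group, for F1 ifosfamide (top) and F2 ifosfamide (bottom) against F1 control. The mitochondrial genome is not drawn, the X chromosome reached 0.189% of its tested windows in F1, and the Y bars stand for 1 window in F1 and 2 in F2.

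The highest 10% of windows held 39.9 ± 0.559% of counts in F1 control, 40.0 ± 0.258% in F1 ifosfamide and 40.1 ± 0.427% in F2 ifosfamide libraries (SD, n = 6). The share of counts on X was 2.83 ± 0.0436% in F2 and 2.74 ± 0.0658% in F1 ifosfamide (exact permutation p = 0.00649, adjusted p = 0.0779), with 4 of 6 F2 libraries above all F1 ifosfamide libraries. The share on MT was 2.26 times as high in F2 as in F1 ifosfamide (exact permutation p = 0.0195, adjusted p = 0.117). No group difference passed the threshold after adjustment over the 12 tests.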

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

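None of the tests behind these values was chosen after the result was seen. In 7 of 132 groups of 6 pools, the highest or lowest pool lay far from the others by Dixon's ratio of its gap to the whole range, where chance gives 6.6. The groups tested were both groups of the comparison that named a window, and all 3 groups for the shares of counts in the highest 10% of windows and on X, Y and MT. All 7 were at named windows. In F1 control these were pool 1 at 50419001 on chromosome 19, with 4.51 CPM against a median of 0.235 in the other pools (ratio 0.933), and pool 3 at 54181001 on chromosome 1, with 3.21 against 1.88 CPM (0.787). In F1 ifosfamide they were pool 1 at 61716001 on chromosome 18, with 0.363 against 0.715 CPM (0.735), and pool 3 at 61168001 on chromosome 7, with 0.746 against 1.04 CPM (0.662). The same was seen in F1 ifosfamide for pool 5 at 108676001 on chromosome 13, with 4.70 against 2.52 CPM (0.840), and pool 6 at 262990001 on chromosome 1, with 0.638 against 1.10 CPM (0.829). In F2 ifosfamide it was pool 1 at 69506001 on chromosome 5, with 0.795 against 0.440 CPM (0.678).

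At 30 of the 40 named windows of the comparisons with the control, 16 from F1 and 14 from F2, F2 and F1 ifosfamide differed from each other by edgeR's quasi-likelihood test. These windows were selected as extremes in pools that this test shares, so a difference back is partly built in, and no value for unchanged groups was computed. Where F1 ifosfamide was below its control, F2 lay above F1 ifosfamide by log2 values of 1.10 at 30735001 and 0.91 at 109827001 on X, 1.77 at 54147001 on chromosome 14, 0.97 at 112120001 and 0.89 at 111855001 on chromosome 10, and 0.83 at 99152001 on chromosome 7. The same held by 1.61 at 39108001 and 0.71 at 51028001 on chromosome 16, 0.93 at 127567001 on chromosome 2 and 1.06 at 49407001 on chromosome 12. Where F1 ifosfamide was above its control, the differences were -0.70 at 61605001 on chromosome 7, -0.49 at 91130001 on chromosome 5, -0.62 at 46330001 on chromosome 14, -0.66 at 11908001 on chromosome 1, -0.72 at 78049001 on chromosome 2 and -0.60 at 57194001 on chromosome 17.

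Among windows higher in F2 ifosfamide than in the control, F2 exceeded F1 ifosfamide by log2 values of 1.77 at 155784001 on chromosome 2, 1.19 at 103428001 on chromosome 9, 1.69 at 7027001 on chromosome 8, 0.82 at 145601001 on chromosome 7 and 0.41 at 11966001 on chromosome 1. It did so by 1.48 at 50419001 on chromosome 19, 1.93 at 36093001 on chromosome 3 and 1.58 at 36270001 on chromosome 4. Among windows lower in F2 ifosfamide than in the control, the differences were -0.99 at 54181001 and -0.93 at 56026001 on chromosome 1, -0.81 at 169329001 on chromosome 3, -1.15 at 141796001 on chromosome 7, -0.92 at 40879001 on chromosome 18 and -0.91 at 75574001 on chromosome 8.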

How the results depend on the processing

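The tests with a within-group component covariate, with a windows-per-read covariate and without the pool farthest from the mean of each group were chosen only after the data were seen. No named window changed direction under any alternative, and 11, 4 and 20 of the 20 named windows of the F1, F2 and generation comparisons stayed called under all that tested them. Some windows had no value under a few alternatives, and fewer alternatives were run for the generation comparison. The numbers of called windows depended far more on the test and on single pools, and changes of 1.5-fold were mostly missed in simulated counts.

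Of windows called between F1 ifosfamide and F1 control (624), there were 1097 at an adjusted p of 0.1 and 173 at 0.01, 333 with DESeq2's Wald test (226 shared), 222 with edgeR's exact test, 229 with limma, 238 with a minimum count of 30 and 1010 with all 3 groups in 1 fit. There were 1938 with the component covariate and 1996 without the farthest pools. With the windows-per-read covariate there were 609, 72.2% of them lower, with 253 shared. At an unadjusted p of 1e-05 and 1e-06 there were 402 and 140. Without any 1 pool the number ran from 159 to 2117, and at p 1e-04 from 596 to 2155.

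Of windows called between F2 ifosfamide and F1 control (286, 171 of them higher), there were 219 with edgeR's exact test (103 higher), 788 at an adjusted p of 0.1 and 55 at 0.01, 27 with DESeq2's Wald test (20 shared), 58 with limma, 46 with a minimum count of 30 (22 higher) and 56 with all 3 groups in 1 fit. There were 86 with the component covariate and 864 without the farthest pools (391 higher). At an unadjusted p of 1e-05 and 1e-06 there were 223 and 67. Without any 1 pool the number ran from 72 to 1501, and at p 1e-04 from 542 to 1751.

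Of windows called between F2 and F1 ifosfamide (22806), there were 45654 at an adjusted p of 0.1 and 5894 at 0.01, 14464 with a minimum row total of 10, 9777 with the component covariate and 44730 with the windows-per-read covariate (22011 higher and 22719 lower, against 13268 and 9538). At an unadjusted p of 1e-05 and 1e-06 there were 2904 and 1196. Without any 1 pool the number ran from 9116 to 37607, and at p 1e-04 from 4433 to 11703. Stricter and looser thresholds change counts by construction, and for the other alternatives the cause was not tested.

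Replicate numbers did not pair the pools. The correlations of same-numbered pools' deviations ran from -0.123 to -0.00894 for F1, from -0.0114 to 0.0597 for F2 and from -0.12 to -0.0119 between generations, and 0, 2 and 0 of 6 correlated best with their own number. With the replicate number as a block the counts were 393, 714 and 14282, and with the block and loess offsets 375 for F1 and 663 for F2.

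The overlap of F1 and F2 calls was 25 for windows within 10 kb. With the controls split into 3 and 3 its median was 0, and the covariance of fold changes turned from 0.0151 to -0.0044. Such splits use fewer controls, share none and always gave control pool 1 to F1. The share of counts in the highest 1% of windows was above that of F1 ifosfamide by 0.322 percentage points in F2 (exact permutation p = 0.0108, unadjusted), where the highest 10% gave p = 0.686, and the cause was not tested. The alternatives set for promoters and gene lists were not run, because no annotation of the genome build was used here.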

Other observations

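The tests of isolated windows, of windows bordering stretches without reads, and those with a within-group component or a windows-per-read covariate were chosen only after the result was seen. On the mitochondrial genome, 14 of 17 windows were higher in F2 than in F1 ifosfamide by edgeR's quasi-likelihood test, the strongest by adjusted p starting at 8001 (log2 fold change 1.23, SE 0.17). The mitochondrial share of counts was small, at 0.00429 ± 0.00251% in F1 control, 0.00285 ± 0.00212% in F1 ifosfamide and 0.00645 ± 0.00221% in F2 ifosfamide libraries (SD, n = 6). Only 2 of 6 F2 libraries lay above all F1 ifosfamide libraries. On the Y chromosome, 8 of 839 windows passed an adjusted p of 0.1 between F1 ifosfamide and F1 control, all lower (odds ratio 9.21, adjusted p = 4.57e-05 by Fisher's exact test), against 1 at 0.05. Between F2 ifosfamide and F1 control 4 of 754 did, also all lower (odds ratio 6.24, adjusted p = 0.0496), against 2 at 0.05. With windows called at 0.05, Y did not pass in either comparison. These mitochondrial and Y windows were chosen after their values were seen. Windows of a sequence as short as the mitochondrial genome move with its share of the library. The share of counts on Y differed little, at 0.116 ± 0.00191% in F1 control, 0.115 ± 0.00296% in F1 ifosfamide and 0.114 ± 0.00368% in F2 ifosfamide libraries. The cause of the lower Y windows was not tested.

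Windows called in F1 ifosfamide were mostly lower than in the control. Loess offsets by abundance left 90.5% of calls lower, against a trend of enrichment with abundance as the cause, and lower calls bordered stretches without reads only 1.23 times as often as matched windows. Outside the named regions, 94 of 552 lower calls were isolated windows, 8.09 times as many as among windows matched on abundance, so reads piled up at repeats collapsed in the assembly may account for part of them, but without isolated windows 458 of 505 calls, or 90.7%, were still lower. Whichever pool was left out, 76.6% to 93.2% of calls were lower, with the lowest share without control pool 3, where 389 windows were called. That argues against a single pool as the whole cause, and a part of the excess from 1 pool stays open. Fragment length stays open too, since with windows per read as a covariate 72.2% of 609 calls were lower and 253 of the 624 calls remained. An effect of the ifosfamide lineage is open as well and cannot be separated here from differences between founder families.

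Between F2 and F1 ifosfamide far more windows were called than in either comparison with the control. With windows per read as a covariate, a stand-in for fragment length, the count was 73.4 times that of F1 against its control in the same model, which argues against fragment length as the cause. With the first component of variation within groups as a covariate the ratio was 5.04 (9777 against 1938), between the bounds set for it, while the F1 count itself rose from 624 and that of F2 against the control fell from 286 to 86, so a gradient among libraries could account for part of the excess. Isolated windows were frequent among higher calls here too, at 397 of 13245, or 5.67 times the number matched on abundance. Generation and the number of males per pool, which differ together between these groups, stay open and untested.

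The clusters on chromosomes 1, 7 and 14 were higher in both ifosfamide groups. If copy number or a haplotype differed between families of this outbred stock, windows in a cluster that were not called could be shifted nearly as far as the called ones. Over clusters and comparisons, their median was 47.4% of that of the called windows, above the 50% set for this explanation on chromosome 7 in both comparisons and on chromosome 1 in F2 and below it otherwise. Called windows were selected for large fold changes, which lowers this percentage, so values below 50% do not count against the explanation. It cannot be told apart from a regional difference in methylation. The same controls enter both comparisons, which keeps a difference peculiar to the control families open. No genotype or input library was used here.

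Pools were also divided in 100 ways per comparison, the real division included, over 1 in 5 of the tested windows. For F1 ifosfamide against F1 control, 3 of 100 divisions gave at least the 167 windows of the real one at an adjusted p of 0.05 (highest other 1568) and 3 gave at least its 230 at p 1e-04 (highest other 906). That is below the 0.05 level, but only some of the possible divisions were drawn, so chance is not firmly excluded there. A division with several times the real number points to a structure among the pools that the groups do not explain. For F2 ifosfamide against F1 control, 5 of 100 gave at least 43 (highest other 836) and 5 gave at least 168 (highest other 525), so chance cannot be excluded. For F2 against F1 ifosfamide only the real division, 1 of 100, gave as many as 4472 (highest other 1559) and 1508 (highest other 772). With 100 divisions, 1 of 100 is the lowest result possible, and here too only some of the possible divisions were drawn. These counts lie above those of the other divisions drawn, which argues against chance only if pools are taken as independent. Pools of a lineage share ancestors, and the labels list fewer F2 ifosfamide males than separate pools would need. That independence is therefore in doubt, and chance is not firmly excluded.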
